A study of Mus musculus with 16 samples.

How the data were processed

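Polysome-associated RNA was pulled down from tagged D1 medium spiny neurons of dissected mouse striatum, purified, amplified with biotin labelling and hybridised to Affymetrix mouse expression arrays, per the labels' protocols. There were 16 arrays, 9 of mice with a homozygous deletion of miR-128-2 in D1 neurons and 7 of littermate controls, all C57BL6/J and 3 months old. Each array's genotype, experimental repeat and replicate number were taken from its title, which calls the replicates biological. The submitters' processing notes name GCOS 1.4 and GCRMA, without saying what each did. The deposited values are log2 expression, and the authors centred them, since the median of each of the 37174 probe sets over the 16 arrays was 0 to within 1e-06. The software that did the centring, and any filter on probe sets before it, are not given in the sources used here. No absolute level remains, so a probe set near the detection floor cannot be told from a bright one, and no filter on dim probe sets could be applied. The authors also deposited a p-value for each probe set, per the file headers that of the genotype term of a model with 2 factors. A linear model with genotype, experimental repeat, their interaction and the ordinary variance gave the same p-values to within 2e-05, so the second factor was taken to be the experimental repeat. The 16 columns of values in that table equal those of the value table to within 1e-06.

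The 62 Affymetrix control probe sets were left out of the tests, leaving 37112. The platform annotation gave 1 gene for 29680 of these, several for 819 and none for 6613. Symbols were updated through gene identifiers to the GRCm38.p6 RefSeq table, which matched 29539 of the 29680. No genome sequence was used, no coordinates are given, and the test of miR-128 seed matches in 3′ untranslated regions that had been planned was not run. Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) with genotype and experimental repeat as terms, two-sided, on 13 residual degrees of freedom before moderation, and called at a Benjamini-Hochberg adjusted p under 0.05. A gene was to be represented by its brightest probe set, which centred values cannot show. The mean over all probe sets of the gene, listed beforehand as an alternative, was used instead, with adjustment over 16206 genes. The planned minimum log2 value of 5 could not be used either, and the plan for that case was to test all probe sets without a filter. A minimum residual SD of 0.075 was at first used for genes instead. The results with it (9 genes, and vascular markers called by camera) and without it (10 genes, and vascular markers not called) had both been seen when the unfiltered version, the planned one, was made the reported one. SE is that of the fitted difference unless stated otherwise. The experimental repeat by genotype interaction was tested in the same way.

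Gene lists were fixed before the data were examined: 30 lists with 677 entries, covering markers of D1 and D2 neurons, striatal projection neurons, interneurons, cortical neurons, astrocytes, oligodendrocytes and their precursors, microglia, vascular cells, and choroid plexus and ependyma. The others covered MAPK/ERK, dopamine receptor cAMP signalling, immediate early genes, ion channels, glutamate and GABA receptors, synaptic scaffolds and release, small RNA and nonsense-mediated decay factors, stress responses, cholesterol, respiratory chain, ribosomal proteins and miR-128 targets named in earlier work. The miRNA host genes and the ribosome tag, with fewer than 3 genes, were given as genes alone. The other 28 lists were tested with limma's camera at a preset inter-gene correlation of 0.01. Beside it stood camera with an estimated correlation and a two-sided exact permutation of the mean list value per array over all 3920 regroupings of genotype within the repeats. Each was adjusted over the 28 lists. Camera with the estimated correlation called 0 lists (smallest adjusted p = 0.13, 4 lists at an unadjusted p under 0.05). List shifts are mean log2 fold changes, with the SE of the array means.

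Named genes followed a rule fixed beforehand. It took up to 10 genes with the largest rise and 10 with the largest fall among called genes with the same sign in both repeats, then Arpp21, R3hdm1, Drd1 and Rpl10a, and for each list its called members or else 1 member. That member was to be the brightest, and was instead the first measured in the order of the list. On simulated data with the spread and repeat effect of these arrays, the test of deletion against control over 16206 genes called 57.7% of 71 genes changed by 0.3 log2, 84.8% of 66 changed by 0.6 and 98.4% of 63 changed by 1, with 9 false calls among the 16006 unchanged. In 20 simulated sets without a genotype effect at most 1 gene and 0 lists were called. Simulated genes were independent of each other, unlike those on the arrays. The changed genes were drawn from all genes, those of little variation included, so the shares called are averages and overstate those for genes of larger spread.

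Alternatives listed beforehand were no repeat term, the replicate number as a block, each repeat alone, quantile normalization, centring each array on its median, array weights, robust moderation, no moderation, leaving out each array in turn, and the other tests of the lists. Moderation with a trend needs expression levels and was run as the robust form alone. Alternatives chosen after seeing the data were leaving out the 2 control arrays with the highest oligodendrocyte marker values, that value as a covariate, the single most variable probe set of a gene, minimum residual SDs of 0.05, 0.075 and 0.1, the model of the deposited p-values, and the miR-128 target list without Szrd1 and Pea15a. Figures were drawn with matplotlib 3.10.9.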

Results

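Polysome-associated RNA of striatal D1 medium spiny neurons was measured in 16 mice on Affymetrix mouse expression arrays. D1 medium spiny neurons are the dopamine D1 receptor-bearing projection neurons of the striatum, and their ribosomes carried a tag, so that the RNA being translated in these cells could be pulled down from the dissected tissue. The 9 deletion mice lacked both copies of miR-128-2 in D1 neurons. The 7 control mice were littermates of the same age that carried the ribosome tag alone. Anything else that the deletion mice carried and the controls did not cannot be told apart from the deletion here. All were killed at 3 months of age. The work was done in 2 experimental repeats, with 4 deletion and 4 control mice in repeat 1 and 5 deletion and 3 control mice in repeat 2. The deposited log2 values were centred on the median of each probe set over the 16 arrays, so they give differences between mice and no absolute level, and the number of arrays limits the precision. The comparison asks which translated RNAs differ in D1 neurons when the microRNA miR-128, which represses the RNAs it pairs with, is no longer made from this locus.

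The mature microRNA was not measured by these arrays. Its host gene, Arpp21, which encodes a cAMP-regulated phosphoprotein of striatal neurons, lay between -0.03 and 0.08 on the deletion arrays and between -0.19 and 0.01 on the control arrays. The difference was 0.10 ± 0.03 log2 (SE), with a limma adjusted p of 0.32 over all genes and 0.0082 adjusted over the list alone. The 5 probe sets of Arpp21 did not move together: 1 differed by 0.39 log2 (adjusted p = 0.062), and the other 4 by 0.10 or less. None is known here to lie in the deleted part, so these values do not check the deletion. R3hdm1, host of the other miR-128 locus, differed by -0.15 ± 0.07 log2 (adjusted p = 0.55, and 0.042 adjusted over the list alone). Its 3 probe sets were unequal too: 1 differed by -0.38 log2 (-0.67 in repeat 1 and -0.07 in repeat 2), and the others by -0.08 and -0.01. With control repeat 1 replicate 3 and control repeat 2 replicate 1 left out, R3hdm1 was at -0.09 ± 0.07 (limma unadjusted p = 0.23) and Arpp21 at 0.08 ± 0.03 (unadjusted p = 0.027), and neither then passed over the list alone. Rpl10a, the ribosomal protein commonly used as the tag, differed by -0.06 ± 0.04 log2 (adjusted p = 0.80).

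10 genes were higher in the deletion mice and 0 were lower. The largest rise was that of Flrt2, a transmembrane protein of cell adhesion and axon guidance, which rose by 1.51 ± 0.22 log2, or 2.85-fold (95% interval 2.06 to 3.95). Samd10 rose by 0.70 ± 0.11 log2, Slc39a11, a zinc transporter, by 0.66 ± 0.08, Sgcb, the beta subunit of the sarcoglycan complex, by 0.64 ± 0.10, and Eml1, a microtubule-associated protein, by 0.64 ± 0.09. Szrd1, which carries a SUZ domain, rose by 0.62 ± 0.08, Sgms1, a sphingomyelin synthase, by 0.59 ± 0.09, and Ptpro, a receptor-type tyrosine phosphatase, by 0.51 ± 0.09. Mgst1, a microsomal glutathione transferase, rose by 0.46 ± 0.07 and Cndp2, a cytosolic dipeptidase, by 0.41 ± 0.07. The Entrez identifiers of these genes, in the same order, were 399558, 229011, 69806, 24051, 68519, 213491, 208449, 19277, 56615 and 66054. In each of these 10 genes all 9 deletion arrays lay above the control mean of their own experimental repeat, and the difference had the same sign in both repeats. The genes were picked from these same arrays, so this pattern follows in part from the selection and is no separate evidence.

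These calls came from limma with genotype and experimental repeat in the model and Benjamini-Hochberg adjustment over 16206 genes. Adjusted p was 0.0076 for Slc39a11 and for Szrd1, 0.025 for Eml1 and for Flrt2, 0.028 for Sgms1, 0.029 for Sgcb, 0.032 for Samd10, 0.034 for Mgst1 and for Cndp2, and 0.0499 for Ptpro. At an unadjusted p under 0.05, 806 genes were higher and 602 lower, where 810.3 in all are expected by chance. At an unadjusted p under 0.01, 247 were higher and 152 lower, against 162.1 expected in all. With control repeat 1 replicate 3 and control repeat 2 replicate 1 left out, these were 119 and 64, and 776 genes in all had an unadjusted p under 0.05. Flrt2 differed by 1.65 log2 in repeat 1 and 1.37 in repeat 2, Szrd1 by 0.76 and 0.47, and Cndp2 by 0.47 and 0.34. Genes just short of the threshold on the lower side were Coro2a (-0.34 log2, adjusted p = 0.053), Dusp11 (-0.35, adjusted p = 0.067) and Hspa2 (-0.57, adjusted p = 0.091), named after their values were seen.

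**Figure D1:**
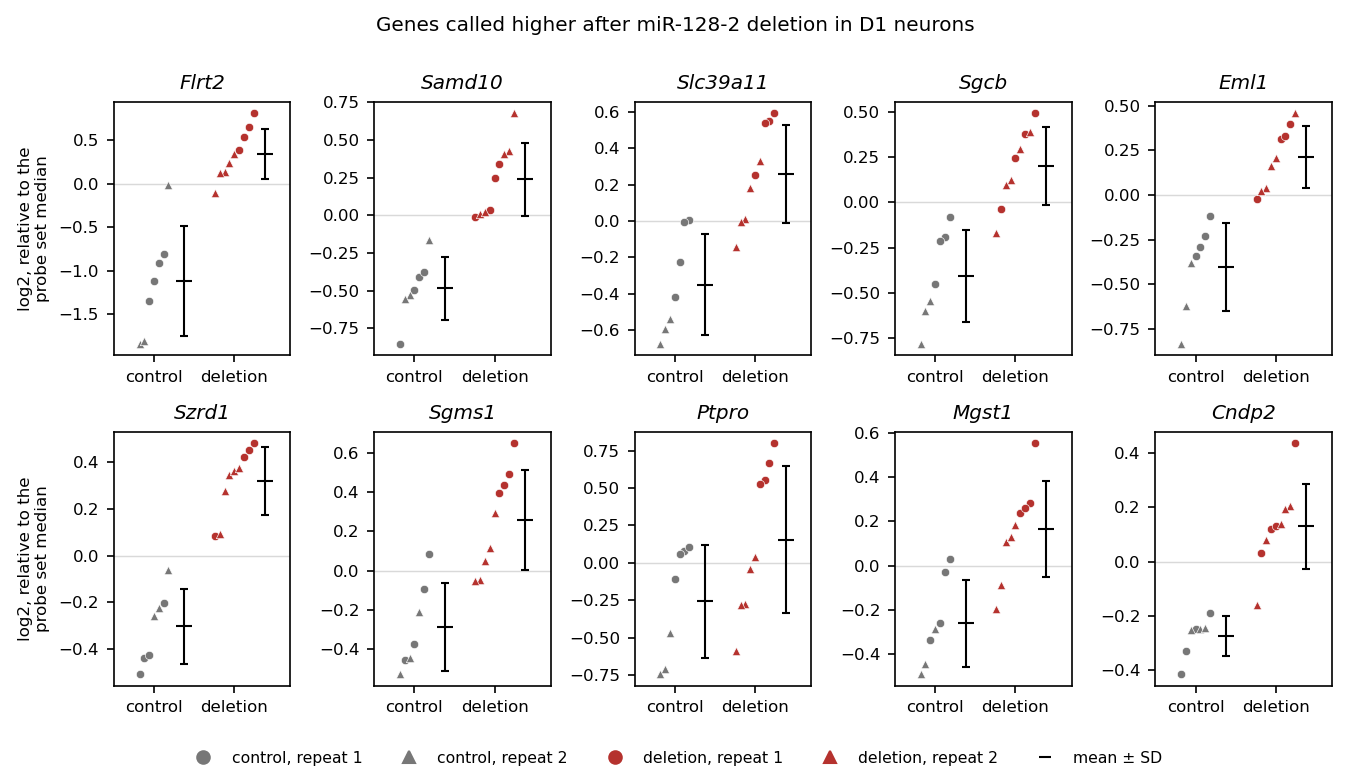
Values of the 10 genes called higher in the deletion mice, 1 point per array, with the control group (7 arrays) on the left and the deletion group (9 arrays) on the right of each panel. The vertical axes give log2 expression relative to the probe set medians, circles and triangles are experimental repeats 1 and 2, and bars give the mean and SD of each group. All 9 deletion arrays lie above the control mean of their own repeat in every panel. Flrt2 has the largest difference, 1.51 log2, but its groups overlap. Its control repeat 2 replicate 3, at -0.01, lies above deletion repeat 2 replicate 5, at -0.11, while the other controls of repeat 2 are at -1.84 and -1.81.

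Counted over probe sets, 11 of 37112 were higher and 1 was lower. The lower one measures Tpp2, a large cytosolic peptidase, and differed by -0.39 ± 0.06 log2 (adjusted p = 0.038), with 0 of 9 deletion arrays above the control mean of their repeat. Ro60, an RNA-binding protein of Y RNA particles, rose by 0.75 ± 0.11 log2 on 1 probe set (adjusted p = 0.038). Tpp2 and Ro60 were named after their values were seen. Slc39a11, Flrt2, Eml1, Cndp2, Sgms1 and Samd10 were each called through 1 probe set, Sgcb through 2, and 2 further probe sets had no gene listed. Probe sets of the same gene were unequal in some cases. For Sgcb, 2 probe sets rose by 0.97 and 0.82 log2, while the other differed by 0.14 (adjusted p = 1.0). For Sgms1, 1 rose by 0.75, while the others, at 0.74 and 0.27, did not pass (adjusted p = 0.089 and 0.69). For Flrt2, 1 rose by 1.31, and the others, at 1.62 and 1.60, did not pass (adjusted p = 0.065 and 0.14). For Cndp2, 1 rose by 0.55, while the other, at 0.27, did not pass (adjusted p = 0.58). Neither probe set of Szrd1 passed alone (0.75 and 0.49, adjusted p = 0.16 and 0.37).

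Control repeat 1 replicate 3 and control repeat 2 replicate 1 stood apart from the other 14 arrays in their content of markers of other cells. Their mean values over 13 oligodendrocyte markers were 1.59 and 1.44, against at most 0.40 elsewhere. Control repeat 2 replicate 1 had the highest 3′ minus 5′ signal of the Gapdh and beta-actin control probe sets as well, a sign of RNA quality, at 1.82 log2, against 0.40 for control repeat 1 replicate 3 and at most 1.17 elsewhere. These probe sets were centred too, so such values compare arrays with each other and give no absolute 3′ to 5′ ratio. Without these 2 control arrays the counts were 1 gene higher and 0 lower, and 0 probe sets. The remaining call was Szrd1 (0.63 ± 0.08 log2, adjusted p = 0.035), and Flrt2 was then at 1.32 ± 0.23 log2 (adjusted p = 0.16) and Slc39a11 at 0.63 ± 0.09 (adjusted p = 0.12). With each array left out in turn, Slc39a11 and Szrd1 passed in all 16 refits, Eml1 and Sgms1 in 9, Flrt2 in 8, Samd10 and Sgcb in 6, Mgst1 and Cndp2 in 3, and Ptpro in 2. The differences moved less than the calls, with Ptpro between 0.48 and 0.56 log2. The count of higher genes was 2 without control repeat 1 replicate 3, control repeat 2 replicate 1 or 2, deletion repeat 1 replicate 2 or 3, or deletion repeat 2 replicate 3 or 4, was 4 without control repeat 1 replicate 1, and was 7 to 10 otherwise.

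Marker genes of D1 neurons rose as a group in the deletion mice. The 7 measured markers were higher by 0.22 ± 0.05 log2 on average (SE of the array means), 6 of them with a positive difference, and the group mean was higher on 9 of 9 deletion arrays than the control mean of the same repeat. None passed over all genes. Adjusted over the list alone 2 of the 7 passed, Pdyn, the dynorphin precursor, at 0.63 ± 0.17 log2, and Slc35d3, a solute carrier, at 0.37 ± 0.08. These and the other genes given below as passing over a list alone were named after their values were seen. Drd1 itself differed by 0.20 ± 0.08 log2 (adjusted p = 0.49, and 0.054 adjusted over the list alone), and Tac1, the substance P precursor, by 0.02 ± 0.03. The shift of the list had a camera adjusted p of 0.00086 (0.13 with an estimated correlation) and an exact permutation p of 0.00077, two-sided (0.011 after Benjamini-Hochberg over 28 lists). It was 0.19 in repeat 1 and 0.25 in repeat 2. Control repeat 1 replicate 3 and control repeat 2 replicate 1 had the lowest values, -0.19 and -0.28, and without them the list was at 0.17 ± 0.05 (exact permutation p = 0.0041, or 0.057 adjusted, above the threshold) and Drd1 at 0.09 ± 0.06.

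Oligodendrocyte markers fell as a group by the preset-correlation test. The mean over 13 genes was -0.39 ± 0.29 log2, all 13 had a negative difference, and none passed alone: Olig2 differed by -0.65 ± 0.29 log2 and Mbp, myelin basic protein, by -0.28 ± 0.22. Camera gave an adjusted p of 0.00097, against 0.58 with an estimated correlation, and the exact permutation of genotype within repeats gave p = 0.25. The shift was -0.32 in repeat 1 and -0.46 in repeat 2, and without control repeat 2 replicate 1 it was -0.17 (camera adjusted p = 0.13). Without both control arrays named above it was 0.07 (adjusted p = 0.46), with the opposite sign.

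Of the other cell type markers, vascular genes had a mean difference of -0.13 ± 0.04 log2 over 7 genes, with 0 of 9 deletion arrays above the control mean of their repeat. The camera adjusted p was 0.073 (0.58 with an estimated correlation), and the exact permutation p was 0.0033 (0.029 adjusted). Esam, an endothelial adhesion molecule, was at -0.32 ± 0.12 log2 and Flt1, a VEGF receptor, at 0.00 ± 0.01 (adjusted p = 1.0), and the list was at -0.07 without the 2 control arrays, where it was no longer called (adjusted permutation p = 0.15). Mean differences with an adjusted camera p above the threshold were -0.24 for cortical glutamatergic neurons (Slc17a7 -0.54 ± 0.25), -0.23 for choroid plexus and ependyma (Ttr -1.52 ± 1.26), -0.17 for striatal interneurons (Sst -0.40 ± 0.22), -0.13 for microglia (Aif1 -0.01 ± 0.02), -0.09 for D2 neurons (Drd2 0.12 ± 0.20), -0.08 for oligodendrocyte precursors (Pdgfra -0.01 ± 0.03), -0.08 for astrocytes (Gfap -0.09 ± 0.16) and 0.06 for striatal projection neuron genes (Ppp1r1b 0.04 ± 0.07). The smallest adjusted permutation p among these 8 lists was 0.50. Of these means 4 had the opposite sign without the 2 control arrays. They were then at 0.10 for D2 neurons, 0.05 for microglia, 0.05 for oligodendrocyte precursors and 0.02 for astrocytes. Flt1 and Aif1 were each measured by 1 probe set that hardly varied (residual SD 0.018 and 0.031). Without absolute levels it cannot be told whether these transcripts were detected, so their small SEs are no evidence of unchanged expression. A residual SD of 0.075 was reached by 4 of 7 vascular and 4 of 8 microglia genes.

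**Figure D2:**
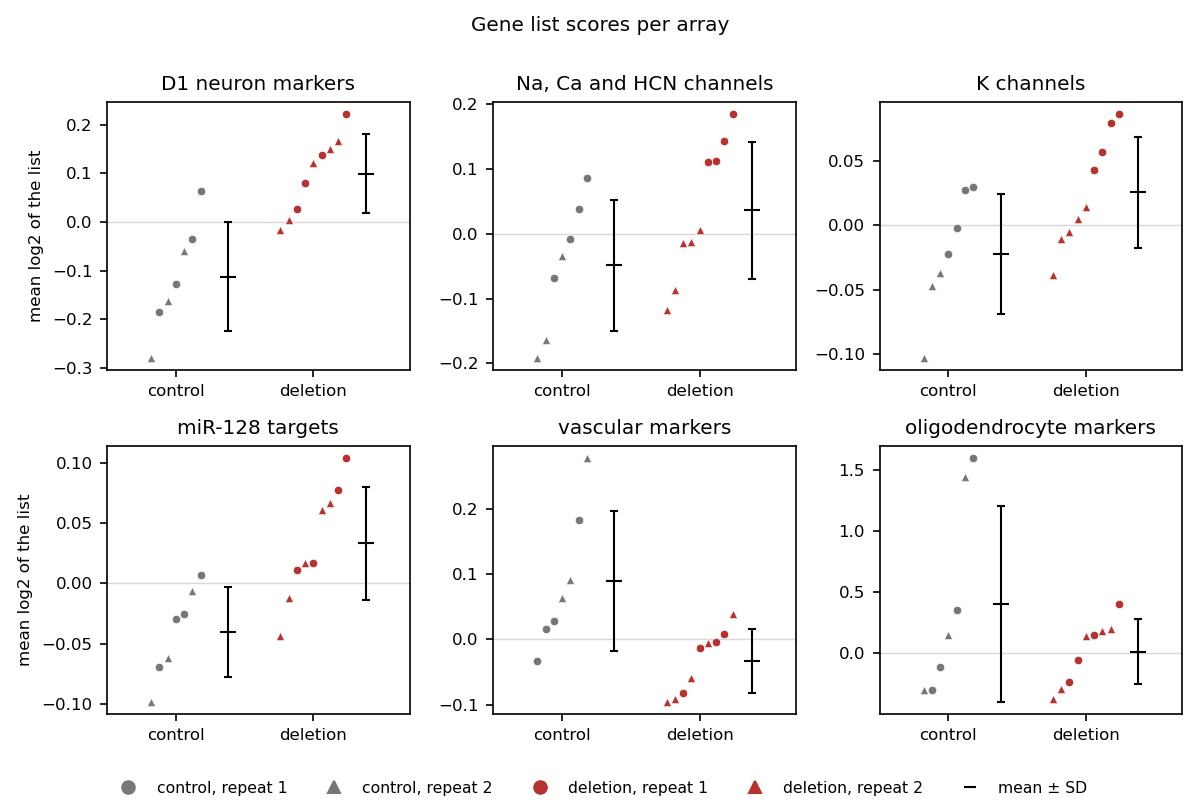
Mean log2 value of 6 gene lists on each array, with the control group (7 arrays) on the left and the deletion group (9 arrays) on the right of each panel, circles and triangles for experimental repeats 1 and 2, and bars for mean and SD. D1 neuron markers lie higher in the deletion group by 0.22 log2, and the oligodendrocyte panel shows 2 control arrays at 1.59 and 1.44, above all others.

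Genes of sodium, calcium and HCN channels and their subunits, in a list that also holds Nalcn, Trpc1, Trpc4 and Trpc5, rose as a group. The 31 measured genes were higher by 0.11 ± 0.03 log2 on average, 25 of them with a positive difference, and the group mean lay above the control mean of its repeat on 9 of 9 deletion arrays. None passed over all genes. Adjusted over the list alone 4 passed: Scn3b (0.36 ± 0.11 log2) and Scn4b (0.18 ± 0.05), both auxiliary sodium channel subunits, Cacna2d3 (0.34 ± 0.10), an auxiliary calcium channel subunit, and Cacng4 (0.22 ± 0.06). Scn1a was at 0.04 ± 0.10. Camera gave an adjusted p of 0.00086 (0.13 with an estimated correlation), and the exact permutation p was 0.0054 (0.030 adjusted). The shift was 0.13 in repeat 1 and 0.08 in repeat 2.

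The 38 measured potassium channel genes had a mean difference of 0.06 ± 0.01 log2, 28 of them positive, above the control mean on 9 of 9 deletion arrays. Their exact permutation p was 0.00051, the smallest of the 28 lists (0.011 adjusted), while camera missed the threshold (adjusted p = 0.073, and 0.13 with an estimated correlation). None of the 38 passed, and Kcna1 was at 0.02 ± 0.07 log2. Glutamate receptors were at 0.07 ± 0.06 log2 over 20 genes (camera adjusted p = 0.073, permutation p = 0.24). Grm8, a metabotropic glutamate receptor, was at 0.58 ± 0.15 and passed over the list alone, and Gria1, an AMPA receptor subunit, was at 0.20 ± 0.07 (adjusted p = 0.39). GABA receptor and synthesis genes were at 0.07 ± 0.06 log2 (Gabra2 0.06 ± 0.18), postsynaptic scaffolds at -0.04 ± 0.05 (Dlg1 -0.02 ± 0.04) and vesicle release genes at -0.02 ± 0.03 (Snap25 0.04 ± 0.07), with no call by camera or by permutation. Without the 2 control arrays the sodium, calcium and HCN channel list was at 0.10 ± 0.03 (exact permutation p = 0.015, or 0.12 adjusted, above the threshold). Potassium channels, at 0.07 ± 0.01, then passed all 3 tests (adjusted p = 0.0018 by camera, 0.032 with an estimated correlation and 0.038 by exact permutation), and glutamate receptors, at 0.12 ± 0.06, passed camera alone (adjusted p = 0.00016, 0.20 with an estimated correlation and 0.15 by exact permutation).

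Among 30 measured genes named in earlier work as targets of miR-128, 16 were higher and 14 lower in the deletion mice, with a mean difference of 0.08 ± 0.02 log2 and a median of 0.00. Szrd1 was the single one called over all genes. Adjusted over the list alone 3 passed, Szrd1 (0.62 ± 0.08), Ntrk3, the receptor of neurotrophin 3 (0.21 ± 0.05), and Pea15a, an ERK-binding phosphoprotein (0.49 ± 0.13, adjusted p = 0.29 over all genes). Upf1, a factor of nonsense-mediated decay, was at -0.37 ± 0.16 (adjusted p = 0.55). Camera did not call the list (adjusted p = 0.079, and 0.28 with an estimated correlation), and the exact permutation p was 0.0041 (0.029 adjusted). Without the 2 control arrays the list was at 0.07 ± 0.02. Camera then called it (adjusted p = 0.035), but not with an estimated correlation (0.20), and the exact permutation no longer did (adjusted p = 0.12). Szrd1 and Pea15a are thought to have entered the list from work on this mouse line, and are then no independent evidence of its direction. The other 28 genes were at 0.04 ± 0.02 log2 (camera adjusted p = 0.28, exact permutation p = 0.092).

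Genes of signalling and housekeeping lists gave no call by camera or by permutation over the 16 arrays. The MAPK/ERK pathway was at 0.03 ± 0.03 log2 over 38 genes, 19 positive and 19 negative (Braf -0.06 ± 0.05). Dopamine receptor cAMP signalling was at 0.03 ± 0.02 (35 genes) and immediate early genes at 0.07 ± 0.08 (27 genes, Fos 0.57 ± 0.29, adjusted p = 0.62). Without the 2 control arrays immediate early genes were at 0.12 ± 0.08 and passed camera (adjusted p = 0.035, 0.53 with an estimated correlation and 0.56 by exact permutation). Small RNA pathway genes were at -0.02 ± 0.04 (Dicer1 0.13 ± 0.10) and nonsense-mediated decay factors at -0.01 ± 0.03, where Ncbp2, a cap-binding protein, was at 0.29 ± 0.07 and passed over the list alone. ATF4 and unfolded protein response genes were at 0.05 ± 0.05 (Atf4 0.06 ± 0.07). Xbp1, a transcription factor of that response (0.34 ± 0.07), and Manf, an endoplasmic reticulum stress factor (0.47 ± 0.11), passed over the list alone. Heat shock genes were at -0.05 ± 0.05, with Hspa1a, an inducible HSP70, at -0.70 ± 0.14 (adjusted p = 0.15, passing over the list alone) and 0 of 9 deletion arrays above the control mean of their repeat. Cholesterol genes were at 0.08 ± 0.07 (Hmgcs1 0.06 ± 0.11), the respiratory chain at 0.04 ± 0.06 (Ndufa1 0.03 ± 0.04) and cytosolic ribosomal proteins at 0.05 ± 0.06 (Rpl4 0.09 ± 0.09). The median difference had the opposite sign to the mean for the MAPK/ERK pathway, dopamine receptor cAMP signalling and ATF4 and unfolded protein response genes, and camera's direction was opposite to the mean for nonsense-mediated decay factors. The smallest adjusted permutation p of these 10 lists was 0.50, and their smallest adjusted camera p was 0.093.

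**Figure D3:**
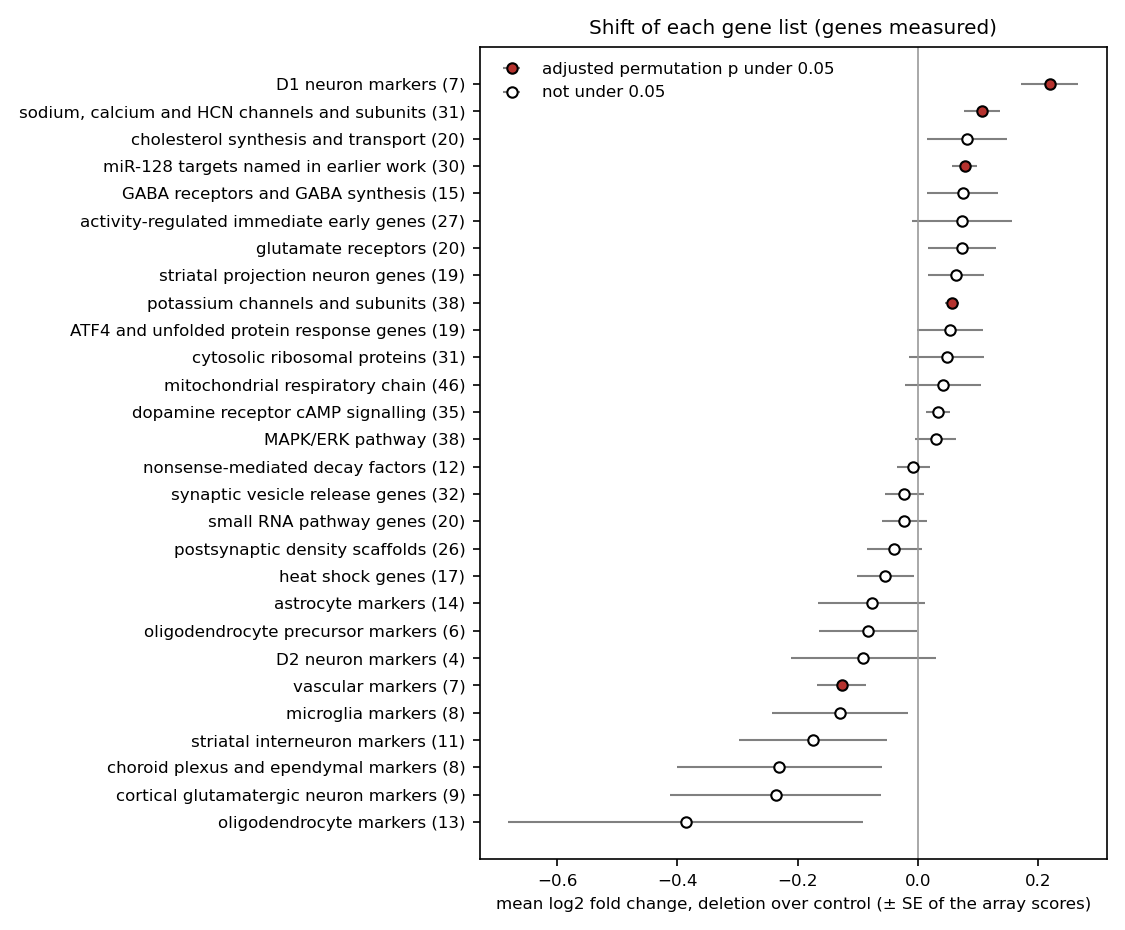
Mean log2 fold change of deletion over control (horizontal axis) for each of 28 gene lists (vertical axis, number of measured genes in brackets), with bars for the SE of the array means. Filled points are the 5 lists with an adjusted exact permutation p under 0.05, among them D1 neuron markers at 0.22 and vascular markers at -0.13, and oligodendrocyte markers have the widest bar, -0.39 ± 0.29.

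Whether the effect of the deletion differed between the 2 experimental repeats was tested by the interaction of genotype and repeat. Of 16206 genes and 37112 probe sets, limma called 0 of either. At an unadjusted p under 0.05 there were 684 genes and 1427 probe sets, fewer than the 810.3 and 1855.6 expected by chance. Immediate early genes had a mean of -0.03 log2 in repeat 1 and 0.18 in repeat 2, MAPK/ERK pathway genes -0.03 and 0.09, and cytosolic ribosomal proteins 0.01 and 0.09. Camera called these 3 differences (adjusted p = 0.012, 0.0095 and 0.041), while exact permutations gave p of 0.20, 0.092 and 0.57. The interaction was called for 3 genes and 17 probe sets without control repeat 2 replicate 1, for 1 gene and 2 probe sets without control repeat 2 replicate 2, for 2 genes and 8 probe sets without control repeat 2 replicate 3, and for 1 probe set without deletion replicate 2 of either repeat.

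The repeats themselves differed in many genes. limma called 2421 of 16206 genes between repeat 1 and repeat 2, and the first principal component, 26.0% of the variance, ran along the repeats.

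The authors' deposited table gives a genotype p-value for each of 37174 probe sets. Of these, 2286 had a p under 0.05 and 571 a p under 0.01, where 1859 and 371.7 are expected by chance, and the smallest was 1.57e-06, for a probe set of Sgcb. After Benjamini-Hochberg adjustment 0 of the values in the authors' deposited table stayed under 0.05.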

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

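The tests that weigh the oligodendrocyte pattern and those without the 2 control arrays were chosen after the results were seen. The tests of RNA quality, of gene length and of other groupings of the mice were chosen before.

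A single array stood far from the rest of its group in 8 of the groups of values tested, or 6.0% of them, where chance gives about 1 in 20. The groups pooled both experimental repeats, and that rate takes a group as uniform, so it is a rough guide. Deletion repeat 2 replicate 2 was lowest in R3hdm1 (-0.48 log2, others at least -0.13) and in Drd2 (-1.12, others at least -0.12), and highest in Pdgfra (0.16, others at most 0.03). Control repeat 1 replicate 2 was lowest in glutamate receptor genes (-0.32, others at least -0.07) and heat shock genes (-0.15, others at least 0.03). Deletion repeat 1 replicate 4 was highest in postsynaptic scaffold genes (0.15, others at most 0.01), deletion repeat 1 replicate 3 lowest in Aif1 (-0.085, others at least -0.021), and deletion repeat 2 replicate 5 lowest in Gria1 (-0.20 log2).

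The effect of the deletion differed between the repeats for 3 lists by camera, by 0.21 log2 for immediate early genes, 0.11 for MAPK/ERK pathway genes and 0.074 for cytosolic ribosomal proteins, each higher in repeat 2. Of 100 groupings of the mice within repeats, the real one included, 74 gave 3 or more such lists, and the highest other count was 15, so chance cannot be excluded. The interaction called 0 genes and 0 probe sets, which all 100 groupings reach, with at most 5 genes and 5 probe sets in the others.

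Counts of genes and probe sets were set against other groupings of the mice as well. The 12 probe sets called between deletion and control were reached by 1 of 100 groupings, the real one, and the highest other count was 1. The 10 called genes were reached by 2 of 100, with 12 in the highest other. The 247 genes higher at an unadjusted p under 0.01 were reached by 4 of 100, and 1 other grouping gave 930. So high a count may arise without the genotype, but another grouping can share part of the real contrast. How far that grouping did so was not examined, and the source of its count was not tested. Without the 2 control arrays the 247 fell to 119, a count for which other groupings were not run. Each of these 3 counts over the 16 arrays was reached by a share of groupings under 0.05. Chance is not excluded by this, since 100 of the 3920 regroupings were drawn and nothing was adjusted for the number of counts tested. The number of lists called by camera at its preset correlation was no larger than in other groupings. Of 100 groupings 74 called the observed 3 or more, up to 13, so the exact permutation p of each list is the safer guide.

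Oligodendrocyte markers were lower in the deletion mice on average, by -0.39 log2, and 2 control arrays stood far above the others. Whether these 2 samples held RNA of oligodendrocytes, which the pulldown should remove, cannot be told apart from a difference in the mice: the medians of the 2 groups differed by -0.0092 (SE 0.16 over the other 14 arrays), but the arrays were picked for their high values, and control repeat 2 replicate 1 had the highest 3′ minus 5′ signal too (1.82). A lower share of D1 neuron RNA alone was weighed by whether other cell types rose alike, though it need not raise every marker by the same log2 amount. The excess over genes of residual SD at least 0.075 was 1.59 for 13 oligodendrocyte markers and 0.38 for 14 astrocyte markers, a gap of 1.20 ± 0.12 (SE). The arrays were picked for their oligodendrocyte values, so this gap cannot decide against a lower share. Over all measured members the oligodendrocyte and astrocyte excess was 1.53 and 0.32. It was 0.59 for microglia, 0.58 for D2 neuron and 0.24 for vascular markers. There the residual SD minimum gave 1.23, 0.58 and 0.82, and the excess itself raises that SD. Interneuron, cortical, oligodendrocyte precursor and choroid plexus markers had an excess of 0.43, 0.41, 0.41 and 0.40 over all members. D1 neuron markers were lower, at -0.27, and striatal projection neuron genes were at -0.08. Of the 13 markers 0 are in another of the lists, and a difference due to the deletion is not excluded.

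D1 neuron markers were higher in the deletion mice by 0.22 ± 0.05 log2. Against RNA of other cells in the 2 control arrays as the whole cause, the difference without them was 0.17 ± 0.05 (exact permutation p = 0.0041 over 735 regroupings). The permutation p adjusted over lists then went from 0.011 to 0.057, past the threshold, with a smaller difference and fewer arrays. Against RNA quality, it was 0.19 ± 0.03 with the 3′ minus 5′ signal of the Gapdh and beta-actin control probe sets as a covariate. That covariate rests on these transcripts alone, so RNA quality is not excluded. That the loss of miR-128 raises these transcripts, or that the pulldown recovered D1 RNA better from deletion mice, stays open and untested.

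Genes of the list of sodium, calcium and HCN channels and subunits were higher by 0.11 ± 0.03 log2. Without the 2 control arrays the difference was 0.096 ± 0.035 (exact permutation p = 0.015), and the p adjusted over lists went from 0.030 to 0.12 with fewer arrays. With the 3′ minus 5′ covariate the difference was 0.106 ± 0.031. The estimate thus changed little in either fit, but neither RNA of other cells nor RNA quality is excluded. The 2 arrays were picked for oligodendrocyte values, such RNA on the other arrays was not weighed, and the covariate rests on Gapdh and beta-actin alone. The genes are long, with a median of 129.6 kb against 21.9 kb for all genes, but the list stood at percentile 100 of 10000 random lists of the same gene lengths, whose highest mean was 0.094. That comparison describes these arrays, since random lists lack the shared regulation of channel genes. The random lists were matched on gene length alone and not on variation between arrays. Genes of little variation can narrow the range of their means, so gene length is not excluded by this comparison. An effect of the deletion may be considered as a hypothesis, and a higher share of D1 RNA in the deletion samples is not excluded.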

How the results depend on the processing

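Alternatives chosen after seeing the data were those without the 2 control arrays, with the oligodendrocyte covariate, the single probe set, the residual SD minimums, the unmoderated interaction model and the shortened target list. Centred values leave signal over background unknown, so floor-level probe sets could not be removed, the planned log2 minimum of 7 could not be run, and the seed-match alternatives were not run. The cause of a moved count was not tested, except that single repeats and left-out arrays test fewer samples.

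Main counts were 11 probe sets higher and 1 lower, 10 genes higher and 0 lower. Probe sets higher and lower, and genes higher, were 1, 0 and 4 without a repeat term, 0, 0 and 2 without moderation, 0, 0 and 3 with the unmoderated interaction model, 4, 2 and 2 with the oligodendrocyte covariate, and 0, 0 and 1 without the 2 control arrays. They were 1, 1 and 0 in repeat 1 alone and 0, 0 and 0 in repeat 2 alone. Array weights gave 22 probe sets higher and 5 lower, and 14 genes higher and 2 lower. Quantile normalization gave 10 and 2 probe sets, and 1 interaction probe set. Centring each array gave 6 probe sets higher, and 8 genes higher with 1 lower. The single most variable probe set gave 2 genes higher. Residual SD minimums gave 9 or 10 genes. All 10 called genes were called with array weights as well, 2 with the oligodendrocyte covariate and 1 without the 2 control arrays. Without those arrays the interaction called 4 genes and 9 probe sets.

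With the replicate number as a block, over 14 arrays, 0 probe sets higher, 0 lower and 1 gene higher were called. The labels do not say that equal numbers pair the mice. Deviations of same-numbered arrays correlated between -0.30 and 0.43, above 0.1 in 3 of 7 pairs. Pairs of unequal number were not compared, so whether the numbers pair the mice is undecided. The blocked shifts were 0.22 for D1 markers, 0.12 for sodium, calcium and HCN channels and -0.43 for oligodendrocyte markers, still called. Camera then called striatal interneuron (-0.23, adjusted p = 0.0047), cortical glutamatergic (-0.33, adjusted p = 0.0047) and glutamate receptor genes (0.09, adjusted p = 0.046) too. The blocked lists were tested at the preset correlation alone. Without the block, interneuron, cortical and glutamate receptor genes each had an adjusted p of 0.58 by camera with an estimated correlation and 0.50 by exact permutation.

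Of the lists, D1 markers kept their direction in these alternatives, and the camera call was lost with an estimated correlation (0.22, adjusted p = 0.13). That of sodium, calcium and HCN channels was lost there (0.11, adjusted p = 0.13) and in repeat 2 alone (0.085, adjusted p = 0.053). Without the 2 control arrays both passed camera at the preset correlation, but neither did with an estimated correlation (adjusted p = 0.20 and 0.14) or by permutation (0.057 and 0.12). Oligodendrocyte markers lost the call with an estimated correlation and by permutation (-0.39, adjusted p = 0.58 and 0.50) and turned to 0.068 without the 2 control arrays. The miR-128 targets gained a call by permutation (0.077, adjusted p = 0.029). Without the 2 control arrays they gained one by camera (0.069, adjusted p = 0.035) and lost that by permutation (adjusted p = 0.12, and 0.20 with an estimated correlation), and they were at 0.043 without Szrd1 and Pea15a.

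Over these alternatives the adjusted p ran from 0.00038 to 0.13 for D1 markers, 5.37e-05 to 0.13 for sodium, calcium and HCN channels, 0.00017 to 0.58 for oligodendrocyte markers and 0.029 to 0.28 for miR-128 targets.

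Leaving out 1 array at a time gave 0 to 16 probe sets higher and 0 to 2 lower, 2 to 10 genes higher and 0 to 1 lower, 0 to 3 interaction genes and 0 to 17 interaction probe sets. List shifts ran from 0.19 to 0.24 for D1 markers, 0.09 to 0.13 for sodium, calcium and HCN channels, -0.53 to -0.17 for oligodendrocyte markers and 0.069 to 0.088 for miR-128 targets. The oligodendrocyte call was lost without control repeat 2 replicate 1 (-0.17, adjusted p = 0.13). The targets passed camera without deletion repeat 2 replicate 1, deletion repeat 1 replicate 3 or control repeat 1 replicate 3 (adjusted p = 0.046, 0.039 and 0.047). Over all alternatives, 1880 values of named genes and lists kept their status, called or not. Of these, 62 changed sign, a count that by definition holds no called value.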
